A study of Caenorhabditis elegans with 2 samples.

How the data were processed

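ChIP-seq was performed on whole hermaphrodite L4 larvae in 2 biological replicates, each precipitated with an antibody to GFP, per the labels. The strain carried a single inserted transgene on chromosome II with the mex-5 promoter, UNC-130 fused to GFP and the tbb-2 3' UTR, and niDf199 on chromosome IV. One label describes the tag as GFP with FLAG, another as eGFP, and the strain description as GFP.

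The deposited files were 8 peak lists in narrowPeak form, 4 on ce11 and 4 on ce10. The authors called peaks on each replicate and on the pooled reads against 1 shared control file, per the deposited text listings, and derived the optimal IDR list from these relaxed lists. The relaxed lists are labelled as peaks and background for input to IDR. Column 7 of each deposited list is the signal value of the authors' peak caller, whose scale is not given in the sources used here. Column 10 is the deposited summit offset in bp from the start of the peak. Column 9 is the deposited −log10 q-value, at its highest value in all 1667 IDR peaks and so not used to rank them. The aligner, the peak caller and the IDR threshold are not given in the sources used here, and the control reads were not used here. With one control behind every list, any shared fault of that control enters both replicates alike. The lists hold no read counts, so the depth per replicate is unknown, and intervals of shares are Wilson intervals at the 95% level that cover counting error over peaks or genes alone. The number of columns of per-sample values that could not be tied to a sample was 0.

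Peaks were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Genes, 5' ends and noncoding classes came from the Ensembl release 115 annotation of WBcel235, the assembly that ce11 names, and sequence and tRNA identities from RefSeq. Only ce11 coordinates were joined to the annotation, and ce10 lists were used for counts and for overlaps among themselves. A summit in overlapping annotations was given to coding exon, 5' UTR, 3' UTR, other parts of a coding gene, noncoding gene and intergenic DNA, in that order. Promoter windows ran from 1000 bp upstream to 200 bp downstream of the 5' end of each gene, and noncoding genes were scored within 500 bp. Mitochondrial peaks were left out of all genome comparisons.

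Chance was set by 1000 circular rotations of the summits along each chromosome with seed 7, which keep their spacing, and the smallest two-sided p they give is 0.0020. Gene lists were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 26 lists, and noncoding classes over 8 classes by rotation, at a threshold of 0.05. Genes in a list were taken as independent in Fisher's test, which neighbouring genes sharing a promoter peak are not, and the rotation test keeps that clustering. The chromosome test drew 100000 multinomial samples, which take summits as independent. With 2 replicates no test between samples was possible, and the spread between them is given as the SD of shares from the 1667 highest peaks of each replicate alone. The named loci were the 25 IDR peaks of highest signal with a summit within 200 bp in both replicates, up to 4 members of each list and class by signal, and unc-130, mex-5, tbb-2, unc-119, prg-1 and unc-129. This rule, the 26 lists and the tests and alternatives were fixed before the data were examined, except those described as added or chosen after the data were seen. Names not found in the annotation were dropped from the fixed lists, 3 of the piRNA pathway, 3 of the heat shock, 1 of the sperm and 1 of the intestine list, and the counts given are of the members found.

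DNA words were counted within 50 bp of each summit and of the points 500 bp to each side, and compared by an exact binomial test on discordant summit and flank pairs, as planned. A first form of this test, which set each summit against the mean of both flanks, was dropped after its values were seen, because a word in either flank counted against the summit and gave small p-values without a difference in frequency. The pair test was then run with each flank as its own pair, and an exact test treating the 3 windows of a summit as exchangeable was added. On simulated windows with equal word frequency, the pair test gave p under 0.05 in 14.5% of 200 runs and the exchangeable test in 5% of 200 runs over 1648 summits, so the second is the better calibrated. Both recovered a word placed in 5% of summits and 1% of flanks in all 200 runs. The p-values of the 6 words were adjusted together by the Benjamini-Hochberg method.

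The other tests were also tested on simulated data. With 15 of 30 members given a summit, all 120 of 120 simulated gene lists were recovered over 19973 genes. Of 400 unchanged lists, 3 were called. The simulated lists were 30 random genes each, set on rotated summits, under which about 1.94% of genes hold one. A false lower call could hardly arise there, and clustered families were not simulated, so the lower calls were not checked this way. Of 40 rotation tests on rotated summits, 0 gave p under 0.05, and all 10 of 10 with 20% of summits moved to gene starts did.

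Alternatives covered a stricter peak threshold (the upper part of the IDR list by signal), each replicate alone, other windows and distances, relaxed-list summits or genes as the comparison, rotation in place of Fisher's test, other words and the ce10 lists. Alternatives without tRNA-proximal summits, outside promoter windows, with the relaxed list as background for noncoding classes and with exchangeable windows were added after the data were seen. The test of peak calling over 21U-RNA regions was first made over all chromosome IV summits and was replaced, after its value was seen, by one outside promoter windows, because IDR and relaxed summits differ in promoter share.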

Results

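The data were ChIP-seq peak lists for UNC-130, a forkhead transcription factor of the nematode Caenorhabditis elegans, from 2 biological replicates that form 1 group. Whole hermaphrodite L4 larvae, collected 48 h after release from L1 arrest, carried UNC-130 fused to GFP under the promoter of mex-5, a gene active in the germline, and chromatin was precipitated with an antibody to GFP. The design has no second condition, so the comparisons below set the peak summits against the rest of the genome and the replicates against each other. The optimal list, made by the authors with the irreproducible discovery rate (IDR) method, held 1667 peaks on the ce11 build. The relaxed lists held 19058 entries for replicate 1, 18463 for replicate 2 and 16959 for the pooled reads. By their label the relaxed lists hold background as well as peaks. Comparisons with them below therefore set IDR summits against weaker peaks and background together. Read depth is unknown, since the lists give no read counts. All coordinates are on ce11, and signal is the authors' own value for a peak, used here only to rank peaks within a list.

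Both replicates gave largely the same strong peaks. Among the 1667 highest peaks of replicate 1, 74.2% had a summit within 200 bp of a summit among the 1667 highest peaks of replicate 2, and the reverse share was 74.0%. On nuclear chromosomes the share was 74.0%, against a mean of 0.748% when the peaks were rotated along their chromosomes (permutation p = 0.0020, the smallest that 1000 rotations can give, two-sided). Of the 1667 IDR summits, 1662 had a summit within 200 bp in the relaxed list of replicate 1 and 1663 in that of replicate 2. The IDR list was derived from these lists, so this match is no separate evidence of agreement between the replicates. The signals of the replicates were correlated across 1640 nuclear peaks (Spearman's rho = 0.626), which are not independent observations. The IDR peaks were the 1667 peaks of highest signal in the pooled list, with a median width of 420 bp and signals from 58.8 to 2563.9. They held 1664 distinct intervals, since 3 intervals, among them that at madf-6, were listed again with another summit. Of these peaks, 1648 lay on nuclear chromosomes and 19 on mitochondrial DNA.

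Several of the strongest nuclear peaks lay upstream of ribosomal protein genes. The peak of highest nuclear signal (717) was at III, 8043801 to 8044167, in intergenic DNA with its summit 532 bp upstream of K12H4.5. It was followed by a peak of signal 561.6 at III, 10759046 to 10759412, 69 bp upstream of tasp-1. The ribosomal protein genes rpl-3 (III, 3867418 to 3867744, signal 478.3), rpl-15 (IV, 654747 to 655108, signal 435.4) and rpl-35 (III, 7854552 to 7854853, signal 430.2) came next, each with an intergenic summit between 285 and 436 bp upstream of the gene. A peak at III, 5172543 to 5172838 lay 50 bp upstream of K10D2.5 (signal 384.4), and one at IV, 12391180 to 12391509 lay between dpm-3 and the ribosomal protein gene rps-23 (signal 369.4), 254 bp and 280 bp upstream of them. The summit at I, 1014292 to 1014740 lay in the 5' UTR of madf-6 (signal 366.8). The peak at I, 10517115 to 10517398 (signal 359.4) had nlp-4 as its nearest coding gene and lay 99 bp upstream of the snoRNA gene F59C6.15. The other 16 of the 25 peaks of highest signal were on mitochondrial DNA.

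UNC-130::GFP summits were concentrated just upstream of protein-coding genes. Of 1648 nuclear summits, 1103 (66.9%, 95% Wilson interval 64.6 to 69.2) lay in a promoter window from 1000 bp upstream to 200 bp downstream of a 5' end, 3.11 times the 21.5% of rotated summits (permutation p = 0.0020, the smallest possible). The share was 64.4% for the highest peaks of replicate 1 alone and 67.4% for those of replicate 2 alone. Summits were most frequent in the bin centred 150 bp upstream of coding 5' ends, at 10.4 summits per 1000 genes. By annotation, 64.3% of summits were intergenic, 17.7% were in introns or other parts of coding genes, 8.80% in noncoding genes, 3.70% in 5' UTRs and 3.70% in 3' UTRs. Coding exons held 1.82% of summits, 0.0721 times what their length would give, and 5' UTRs held 2.60 times what theirs would give. Among the 15195 nuclear summits of the pooled relaxed list more than 200 bp from an IDR summit, 31.9% lay in promoter windows (odds ratio 4.31, Fisher's exact p = 2.2e-166, two-sided).

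**Figure D1:**
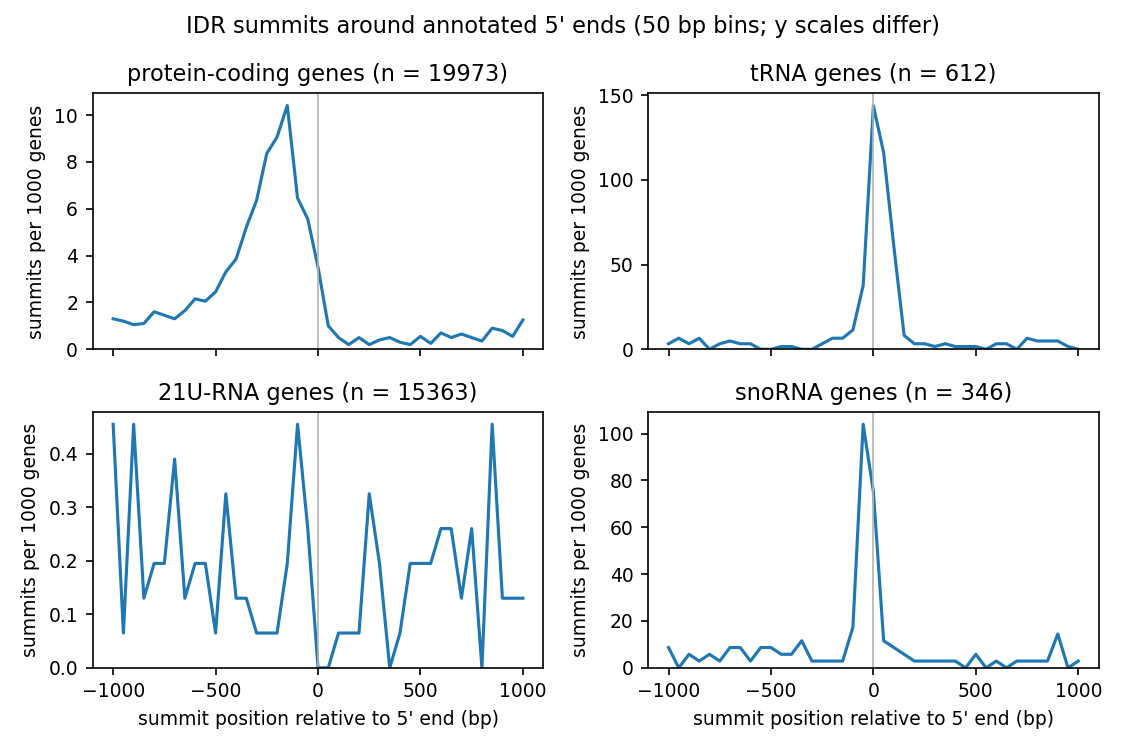
Position of IDR summits relative to annotated 5' ends, in 50 bp bins from 1000 bp upstream (negative) to 1000 bp downstream, as summits per 1000 genes, for 4 gene classes with differing y scales. Summits peaked 150 bp upstream of coding genes at 10.4 per 1000 and at the 5' end of tRNA genes at 143.8, while no bin of the 21U-RNA genes exceeded 0.456.

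Genes for ribosomes, the germline and cell division carried summits far more often than other coding genes. In all, 1568 of 19973 protein-coding genes (7.85%, Wilson interval 7.49 to 8.23) had an IDR summit in the promoter window, against 1.94% under rotation. Ribosomal protein genes had summits at 52 of 76 members (68.4%, Fisher's exact adjusted p = 2.4e-38), and the share over both replicates taken alone was 67.8% ± 0.930 (SD, n = 2). Germline and P granule genes had summits at 19 of 40 (47.5%, Fisher's exact adjusted p = 2.1e-10), with 42.5% ± 3.54 (SD, n = 2). Cell cycle and DNA replication genes had summits at 15 of 30 (50%, Fisher's exact adjusted p = 8.1e-09), with 43.3% ± 9.43 (SD, n = 2). The tests were two-sided with Benjamini-Hochberg adjustment over 26 lists fixed before the data were examined. Of these, 6 were higher than other genes and 8 lower. Control reads were not used, so general enrichment of open, highly transcribed DNA was not tested for promoters or for these lists.

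Among germline genes, the highest signals were at mex-5, which sets up polarity in the zygote, at hrde-1, a nuclear Argonaute of the germline, at pos-1, an RNA-binding protein of early embryos, and at rme-2, the yolk receptor of oocytes. The mex-5 summit (IV, 13353228 to 13353647, signal 168.7, rank 156) lay in the intergenic DNA that mex-5 shares with rec-8, a meiotic cohesin, 285 bp and 245 bp upstream of them. The hrde-1 summit (III, 4176197 to 4176616, signal 165.2), the pos-1 summit (V, 8413623 to 8414042, signal 152.3) and the rme-2 summit (IV, 5469727 to 5470146, signal 138.9) were also intergenic. Other germline members with a summit included oma-1, oma-2, gld-1, glp-1 and pie-1. Of 30 meiosis genes, 8 had summits (26.7%, adjusted p = 0.0045 by Fisher's exact test). The highest signals were at syp-4 (I, 6847215 to 6847409, signal 196.6), a synaptonemal complex protein, rec-8 (168.7), coh-4 (V, 4175605 to 4176024, signal 164.3) and coh-3 (V, 14457046 to 14457465, signal 118). The syp-4 summit lay inside the snRNA gene H27M09.6, 27 bp from its 5' end and 235 bp upstream of syp-4. The rec-8 peak is the mex-5 peak above, counted in both lists, and the transgene carries a copy of the mex-5 promoter.

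Cell cycle members with the highest signals were lin-35, the worm retinoblastoma gene (I, 5807421 to 5807618, signal 239.8), the replication genes psf-1 (II, 9968429 to 9968633, signal 219.2) and pcn-1 (IV, 4049586 to 4049792, signal 172), and the helicase subunit gene mcm-2 (II, 12006670 to 12007089, signal 163.1). All of mcm-2, mcm-3, mcm-4, mcm-5, mcm-6 and mcm-7 had a summit. Of 30 chromatin regulators, 8 had summits (26.7%, adjusted p = 0.0045 by Fisher's exact test), led by the histone methyltransferase gene set-2 (III, 4930323 to 4930583, signal 303), lin-53 (I, 9619911 to 9620053, signal 184.2), the histone variant gene htz-1 (IV, 4445732 to 4446151, signal 146.5) and lin-9 (III, 8904236 to 8904348, signal 137.6). Of 19 heat shock genes, 6 had summits (31.6%, adjusted p = 0.0061 by Fisher's exact test). These were the mitochondrial chaperone genes hsp-60 (III, 1618993 to 1619253, signal 267.4) and hsp-6 (V, 4826949 to 4827368, signal 115.7), hsp-1 (IV, 17278490 to 17278619, signal 149), hsp-110 (III, 8446957 to 8447376, signal 118.8), and hsp-3 and hsp-4 of the endoplasmic reticulum. The hsp-60 summit lay 644 bp upstream of hsp-60 and was nearer to the coding gene Y22D7AL.10, 169 bp upstream of it. None of the hsp-16 genes on the list, which heat induces, had a summit. The heat shock call was lost with a window of 500 bp upstream (21.1%). Against genes with any summit of the pooled relaxed list, only ribosomal (adjusted p = 5.0e-16), cell cycle (0.0010) and germline (0.0028) lists stayed higher by Fisher's exact test, while heat shock (0.148), meiosis (0.894) and chromatin (0.894) lists did not pass.

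Large gene families with restricted expression carried few summits. Chemoreceptor genes had summits at 8 of 1312 members (0.610%, adjusted p = 1.7e-35), nuclear hormone receptors at 4 of 269 (1.49%, adjusted p = 3.1e-05), F-box and MATH genes at 10 of 395 (2.53%, adjusted p = 4.7e-05), C-type lectins at 5 of 240 (2.08%, adjusted p = 0.00076) and neuropeptides at 1 of 140 (0.714%, adjusted p = 0.00076), all lower than other genes by Fisher's exact test. Detoxification genes of the cyp, ugt and gst families (6 of 185, 3.24%, adjusted p = 0.0397), major sperm proteins (0 of 53, Wilson upper bound 6.76%, adjusted p = 0.0411) and collagens (5 of 156, 3.21%, adjusted p = 0.0458) were also lower by Fisher's exact test. With the highest peaks of replicate 1 alone, the calls of collagens, major sperm proteins and detoxification genes were lost and 5 lists stayed lower, and with those of replicate 2 alone the call of detoxification genes was lost. In the upper part of the IDR list by signal the calls of these 3 lists and of C-type lectins were lost, and that of major sperm proteins also with a window of 500 bp upstream and without tRNA-proximal summits. Members with a summit included sre-23 (signal 145), nhr-142 (121), math-33 (120.4), clec-88 (156), ugt-12 (173), col-71 (169) and flp-23 (72.3). The flp-23 summit lay in a noncoding gene, and without tRNA-proximal summits no neuropeptide gene had one. Against rotated summits, chemoreceptors alone stayed lower (adjusted p = 0.0297, permutation test), while collagen, lectin, F-box and detoxification shares were above the rotated ones without passing the test. Against genes in the relaxed list, chemoreceptors (adjusted p = 0.0129) and neuropeptides (0.0340) stayed lower by Fisher's exact test.

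Somatic tissue markers, forkhead genes and ceh homeobox genes did not pass the test. No summit lay in the window of any of 26 body wall muscle, 17 pharynx, 27 intestine, 28 hypodermis and cuticle or 15 forkhead genes, and the Wilson upper bounds of these shares were 12.9%, 18.4%, 12.5%, 12.1% and 20.4%. Single members of other lists had a summit, namely unc-11 among 26 neuronal genes, ced-5 (IV, 10483675 to 10484094, signal 155.2) and unc-40 (signal 91.4) among 30 migration and basement membrane genes, and daf-2 (signal 63.1) and daf-18 (signal 60.8) among 30 insulin pathway genes. Neither daf-2 nor daf-18 was among the highest peaks of replicate 1 alone, where no insulin pathway gene had a summit. Of 13 piRNA pathway genes found in the annotation (3 further names were not), tofu-1 (V, 9980829 to 9981248, signal 105.5) and tofu-6 (II, 5420946 to 5421365, signal 89.7) had a summit (15.4%, adjusted p = 0.393 by Fisher's exact test). Sperm genes (spe-39 and spe-6 of 25), histones (4 of 72, led by his-67 and his-68 with 184.1) and ceh homeobox genes (ceh-38, ceh-92 and ceh-2 of 63) were also not told apart from other genes, with adjusted p of 1, 0.779 and 0.663 by Fisher's exact test.

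**Figure D2:**
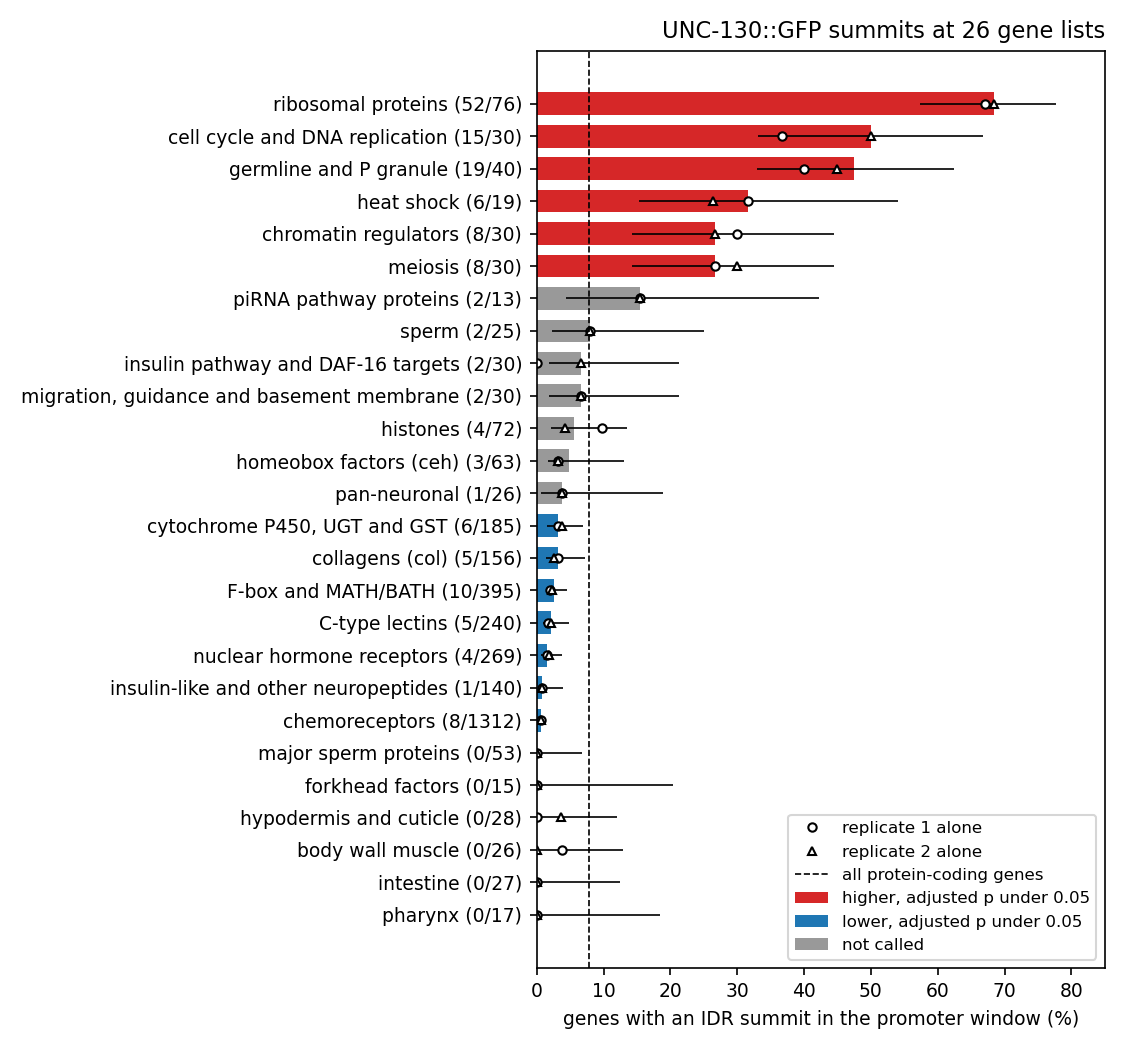
Percentage of genes with an IDR summit in the promoter window for 26 gene lists, with counts in brackets, bars for both replicates combined, 95% Wilson intervals as lines and open symbols for the highest peaks of each replicate alone. Ribosomal protein genes reached 68.4% and chemoreceptors 0.610%, against 7.85% of all protein-coding genes (dashed line), and major sperm proteins, at 0, were called lower although no bar is visible.

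Summits lay near several classes of short noncoding genes more often than under rotation, among them tRNA, snoRNA and snRNA genes. A summit lay within 500 bp of the 5' end of 252 of 612 tRNA genes (41.2%, Wilson interval 37.3 to 45.1), 32.1 times the rotated share, and the replicates alone gave 40.4% ± 4.51 (SD, n = 2). snoRNA genes had summits at 95 of 346 (27.5%, 15.4 times rotation) and 26 snRNA genes had one (20.2% of the class, 12.2 times). miRNA genes (13 of 261, 4.98%, 3.37 times), the annotated ncRNA class (377 of 7764, 4.86%, 3.45 times) and lincRNA genes (8 of 194, 4.12%, 2.56 times) were higher by less. Adjusted over 8 classes, the permutation p was 0.0032 for tRNA, snoRNA, snRNA and ncRNA genes, the smallest these rotations gave, 0.0053 for miRNA and 0.0388 for lincRNA genes. None of 20 nuclear rRNA genes had a summit. In the upper part of the IDR list by signal, the tRNA share fell to 14.7%, below the 20.5% of snoRNA genes, and among genes in the relaxed list tRNA genes stood at 47.1% and snoRNA genes at 52.5%. With only the 545 summits outside every coding promoter window, a choice made after the data were seen, tRNA genes stayed at 31.2%, snoRNA genes at 17.3% and snRNA genes at 11.6%, while lincRNA genes no longer passed (adjusted permutation p = 0.192). Against genes in the relaxed list, a comparison also chosen later, miRNA (adjusted p = 0.124) and lincRNA (1) genes did not pass Fisher's exact test, and the ncRNA class was lower than the other classes (0.0139).

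Among these, the peak with the highest signal at a snoRNA gene was the one at F59C6.15 (359.4), followed by F39B2.14 (I, 14759411 to 14759671, signal 261.5). For snRNA genes the highest were H27M09.6 (I, 6847215 to 6847409, signal 196.6), in the same peak as syp-4, and the spliced leader gene sls-2.1 (II, 5844633 to 5845052, signal 190.3). The miRNA genes with the highest signals were mir-4932 (signal 248.8, in a peak whose summit was nearer to the coding gene klp-16), mir-5549 (155.7), mir-51 (IV, 11025951 to 11026370, signal 120) and mir-35 (II, 11537140 to 11537559, signal 110.9), the last from a family needed in embryos. The tRNA peak of highest signal (V, 15464991 to 15465410, signal 182.1, rank 124) covered a pair of tRNA genes and had its summit between them.

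The 21U-RNA loci, which give the piRNAs of the germline, lay near summits less often than chance over the whole genome. UNC-130 has been linked to the promoters of these genes, and this was the question the locus comparison addressed. Only 31 of 1648 summits (1.88%, Wilson interval 1.33 to 2.66) lay within 500 bp of a 21U-RNA locus, 0.376 times the 5.01% of rotated summits (permutation p = 0.0020, the smallest possible). Of 15363 loci, 44 (0.286%) had a summit that near. On chromosome IV, which holds 14714 of the loci, 18 of 299 IDR summits (6.02%) were near a locus, against 11.5% of 2566 other relaxed-list summits (Fisher's exact p = 0.0032, two-sided) and 24.2% of the bases. IDR summits lie in promoter windows more often, and with summits inside and outside these windows compared apart, neither difference passed Fisher's exact test (4.48% against 6.74%, p = 0.326, and 9.18% against 13.6%, p = 0.284, split after the data were seen). On I, II and III the shares near a locus (1.46%, 1.28% and 0.877%) were above those of the bases (0.636%, 0.704% and 0.560%), and none differed from the relaxed list by Fisher's exact test (p = 0.100, 0.297 and 0.740). On V no summit of 242 was near a locus, and on X 1 of 110 was. Of the 31 summits, 19 lay in a coding promoter window and 8 near a tRNA gene. The locus with the highest signal was 21ur-13751 (II, 1320550 to 1320713, signal 206, rank 80), followed by 21ur-11261 (IV, 5364138 to 5364557, signal 148.8).

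Summits were unevenly spread over chromosomes and rare on X. Relative to length, chromosome III had 1.51 times, I 1.38 times and II 1.25 times the expected number, IV 1.04 times, V 0.704 times and X 0.378 times, with 110 summits on X (chi-square 253.4, Monte Carlo p = 1e-05, the smallest that 100000 multinomial draws can give, with summits taken as independent). A summit lay in the promoter window of 13.7% of coding genes on III and 12.02% on I, but of 30 of 2731 (1.10%, Wilson interval 0.771 to 1.56) on X. The tRNA genes of X did not share this, since 109 of 276 (39.5%) had a summit there and 143 of 336 (42.6%) on autosomes (Fisher's exact p = 0.458, odds ratio 0.881). With the relaxed list as the expectation, II was highest at 1.15 times, IV and III stood at 1.07 times, I at 1.04, V at 0.891 and X lowest at 0.623 times (chi-square 38.3, Monte Carlo p = 1e-05).

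**Figure D3:**
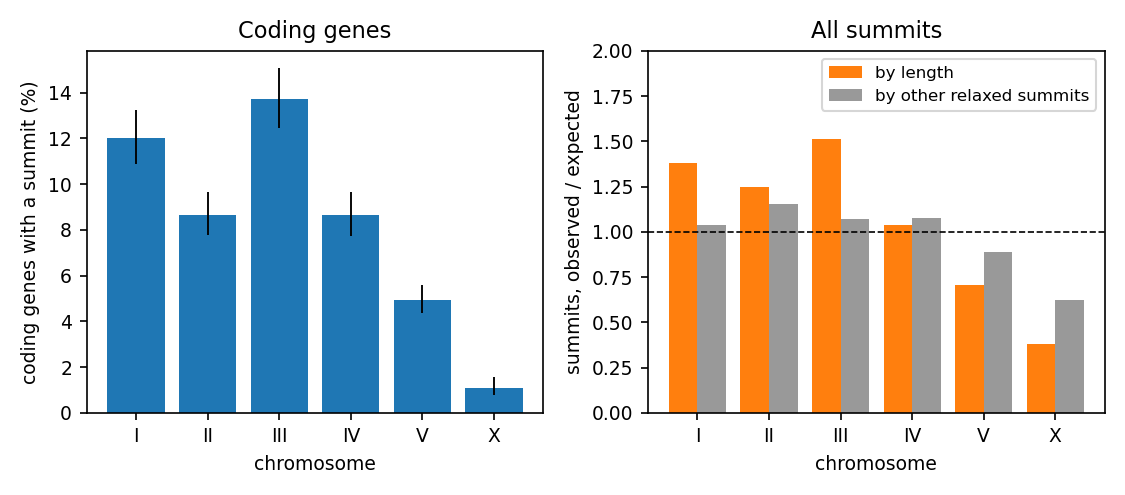
Left, percentage of protein-coding genes on each chromosome with an IDR summit in the promoter window, with 95% Wilson intervals. Right, observed over expected summits per chromosome, expected from length or from the other summits of the pooled relaxed list; X was lowest at 1.10% of genes, 0.378 by length and 0.623 by the relaxed list.

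The general forkhead word was not enriched at summits, and a stricter one was. RTAAAYA, the forkhead consensus, occurred within 50 bp of 9.22% of summits and in 8.74% of windows centred 500 bp to each side (ratio 1.06, exact binomial p = 0.519 on discordant pairs, and 0.596 in an exact test treating the 3 windows of a summit as exchangeable, both two-sided and adjusted over 6 words). TGTTTAC, a strict form, occurred at 37 of 1648 summits (2.25%, Wilson interval 1.63 to 3.08) and in 0.728% of flanks (ratio 3.08, exact binomial adjusted p = 8.4e-07 and exchangeable-window exact adjusted p = 3.1e-05). The second test was added after the data were seen, because the first uses each summit in 2 pairs and was too lenient on simulated windows. Of those 37 summits, 10 were near tRNA genes, and in all 10 the word lay inside the tRNA gene itself. Away from tRNA genes the word occurred at 27 of 1429 summits (1.89%) and in 0.770% of flanks (exchangeable-window exact p = 0.0021, unadjusted). The repeat GAGAGA was more frequent at summits (11.8% against 6.55%) and the GATA word TGATAA less frequent (4.79% against 9.19%), with exchangeable-window exact adjusted p of 4.4e-09 and 5.5e-08. CTGTTTCA, the core of the 21U-RNA upstream motif, was at only 2 of 1648 summits (0.121% against 0.668% of flanks, exchangeable-window exact adjusted p = 0.0102). Its ratio was 0.182, but 0.526 and 0.348 for the highest peaks of replicate 1 and replicate 2 alone. The reversed control AYAAATR was also lower at summits (9.04% against 11.2%, exchangeable-window exact adjusted p = 0.0257). GC content was 45.04% in summit windows and 38.1% in flanks. The comparison with flanks therefore does not separate a word from base composition. Near-equal shares of RTAAAYA do not exclude an excess beyond composition, and TGTTTAC had no reversed control.

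**Figure D4:**
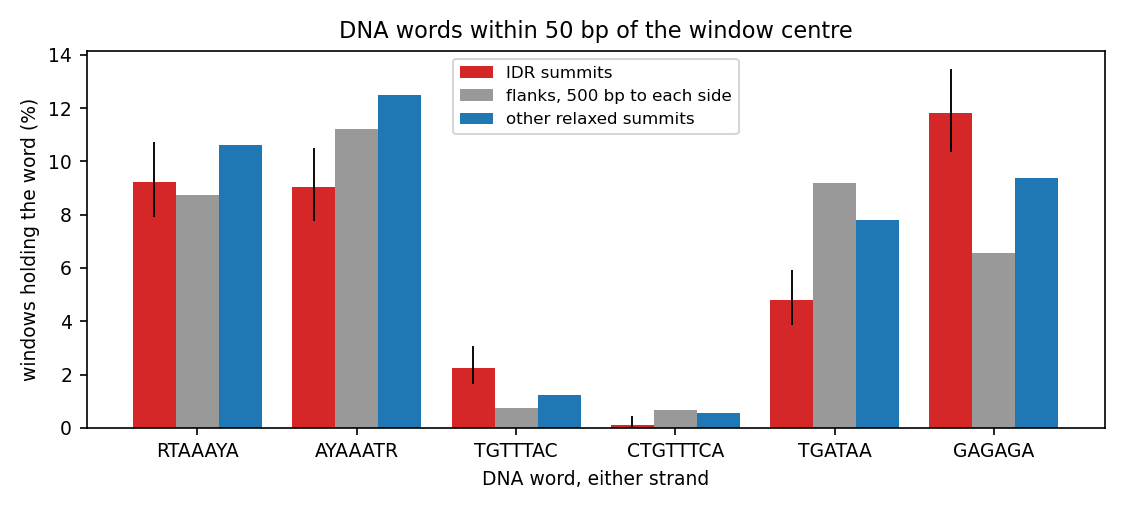
Percentage of windows holding each DNA word on either strand within 50 bp of IDR summits (95% Wilson intervals), of points 500 bp to each side and of other summits of the pooled relaxed list. TGTTTAC was at 2.25%, 0.728% and 1.24%, and RTAAAYA at 9.22%, 8.74% and 10.6%.

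Loci sharing sequence with the transgene gave mixed results. The IDR list held no peak within 1000 bp of unc-130 itself (II, 11281966 to 11283959), and in the relaxed lists of single replicates only replicate 1 had peaks there, the highest with signal 9.92. The mex-5 promoter held the peak at rank 156 described above, and a peak overlapping the 3' end of tbb-2 (III, 4015547 to 4015966, signal 124.2, rank 397) had its summit beyond the annotated end of tbb-2, in the 3' UTR of a neighbouring gene. The transgene carries a copy of the mex-5 promoter, and reads from the 2 copies cannot be separated in these lists. No IDR peak lay near unc-119, prg-1 or unc-129. A pooled relaxed peak by the 3' end of prg-1 (signal 57.3, rank 1755) fell just under the lowest IDR signal of 58.8. The highest peak there ranked 1116 in replicate 1 and 1745 in replicate 2.

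The same libraries on the ce10 build gave 1942 IDR peaks, 275 more than on ce11. The additional peaks were spread over all 6 nuclear chromosomes, with 405 on I against 342 and 139 on X against 110, while mitochondrial DNA had 19 in both. Median peak width in replicate 1 was 416 bp on ce10 and 424 bp on ce11, and the relaxed list of replicate 1 held 19230 peaks on ce10. Replicate signals were correlated at rho = 0.631 across 1911 peaks on ce10, which are not independent observations.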

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

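In this part, 5 tests were chosen after the result was seen: peak calling over 21U-RNA regions at any threshold, coverage of mitochondrial DNA, the position of TGTTTAC in tRNA genes, the summit share of tRNA genes holding it, and IDR summits on X among genes with a relaxed summit.

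Peaks on mitochondrial DNA were outside the nuclear comparisons and stood out by their signal. There were 19 such IDR peaks, among them the 10 peaks of highest signal in the list (1 interval listed with 2 summits among them), with a median signal of 805 against 86.7 for nuclear peaks. They covered 54.5% of the 13794 bp molecule, against 0.633% of the nuclear genome.

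Summits at tRNA genes made up 219 of 1648 (13.3%), with a median distance of 35 bp from the 5' end. Neighbouring coding promoters do not account for most of them, since 74.9% (Wilson interval 68.8 to 80.2) lay outside every coding promoter window. For reads shared between identical copies, the bound set beforehand as evidence against them was met. Of 143 single-copy tRNA genes, 25.9% had a summit against a highest rotated share of 5.59%, although genes with identical copies reached 45.8%. A summit within 500 bp may belong to a neighbouring tRNA gene, and near-identical copies count as single. The test therefore cannot exclude shared reads. General enrichment of open, highly transcribed DNA stays open: TGTTTAC was at 4.57% of these summits against 0.457% of their flanks, which had been set beforehand as evidence against it, but all 10 hits lay inside tRNA genes, so the excess may be tRNA sequence and that bound was wrongly chosen. tRNA genes holding the word had a summit at 14 of 22, against 238 of 590 others (Fisher's exact p = 0.0447, unadjusted, with identical copies counted as separate genes), and no biological explanation was tested, since the design has 1 group.

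The low share of summits at 21U-RNA loci was not explained by loci lying outside coding promoter windows alone. On chromosome IV, among 98 summits outside promoter windows, 9.18% were near a locus, below the 18.8% to 31.9% of 95% of rotations restricted in the same way. These rotations take every base outside the windows as equally open to a summit, so distance beyond the window and regional summit density were not tested. Poor peak calling over these regions at any threshold stays open, since outside promoter windows the relaxed share of 13.6% was also below that range and was not told apart from the IDR share (Fisher's exact p = 0.284). The allele niDf199 on chromosome IV, whose extent is not given in the sources used here, was not tested, and no biological explanation was tested.

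The low number of summits on X was not explained by fewer genes there, since 1.10% of X coding genes had a summit against 8.92% of autosomal ones (Fisher's exact p = 1.3e-64). Leaving out the ribosomal, germline, meiosis, cell cycle and chromatin lists left 1.10% of 2720 X genes against 8.42% of autosomal genes (Fisher's exact p = 5.7e-59). These lists were too small to close that gap, since autosomal genes with a summit went from 1538 of 17242 to 1436 of 17047. The comparison therefore says only that the small number of their members on X is not the whole cause. Among genes with any relaxed summit, 6.55% of X genes and 27.4% of autosomal genes had an IDR summit (Fisher's exact p = 4.0e-28). A scarcity of other germline or broadly expressed genes on X was not tested, nor was any biological explanation.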

How the results depend on the processing

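The alternatives without tRNA-proximal summits, outside promoter windows, with relaxed-list background for noncoding classes and with exchangeable windows were chosen after the data were seen; the others were planned. Promoter share, and the 21U-RNA share against rotation, kept their direction and side of the threshold under every alternative run for them. The 21U-RNA comparison with relaxed-list summits on chromosome IV (Fisher's exact p = 0.0032) did not hold when split by promoter window. Fisher's exact p was then 0.326 inside the windows and 0.284 outside, in a split made after the data were seen. Noncoding classes called went from 6 higher and 1 lower to 3 and 2 with relaxed-list background and 4 and 1 within 200 bp, where miRNA genes were lost, and lincRNA genes were lost under every alternative but without replicate 1. Across all main results, 32 values stayed within the bounds set for them, 10 moved, 3 reversed and 2 became stronger. The upper part of the list by signal held 833 peaks by construction. Replicate overlap was 76.4% with fewer top peaks, 68.7% by reciprocal overlap and 69.2% within 100 bp. Set against the relaxed list, chromosomes stood at 1.04 (I), 1.15 (II), 1.07 (III), 1.07 (IV), 0.891 (V) and 0.623 (X). Lists called numbered 5 with relaxed-list genes as background and 7 under rotation. The forkhead word ratio was 0.868 against relaxed summits, 0.928 in the upper part by signal and 0.997 to 1.13 without 1 replicate. It was 1.21 in wider windows and 3.08 for TGTTTAC, and these 2 passed the threshold, which the main comparison did not. For the wider windows no exchangeable-window result is given, and the pair test was too lenient on simulated windows. Shares of lists and classes kept their direction and side in 208 cases, weakened in 29 and reversed in 19. Reversed under rotation, as a percentage of genes with a summit, were C-type lectins 2.08, F-box and MATH 2.53, collagens 3.21, detoxification 3.24, histones 5.56, ceh 4.76, insulin pathway 6.67, migration 6.67 and neuronal 3.85. These shares are those of the main comparison, and only the reference changed. Of all coding genes, 7.85% had a summit, against 1.94% under rotation, and each of these lists lay between its 2 references. Reversed against relaxed-list genes were insulin pathway 33.3, miRNA 14.6, migration 28.6, ncRNA 20.6, piRNA pathway 18.2 and sperm 22.2. Migration (6.67) and sperm (0) reversed in the upper part by signal, migration (6.67) with a 500 bp window, and histones without replicate 2 (9.72), but not without replicate 1 (4.17). The cause of the reversals other than those under rotation was not tested. Of 71 named summits, 58 stayed in the upper part by signal, 67 without replicate 1 and 65 without replicate 2. Read depth is unknown, so its effect on these values was not tested.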

Other observations

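The 10 gene lists in this paragraph were chosen after the data were seen, and their Fisher's exact tests were adjusted over these lists alone. Genes for several basic cell machines carried summits more often than other coding genes. General enrichment of open, highly transcribed DNA was not tested for them. Sm and Sm-like proteins, which form the cores of spliceosomal RNA particles, had summits at 8 of 14 genes (57.1%, adjusted p = 1.4e-05 by Fisher's exact test), among them snr-2, snr-3 and lsm-1. Genes of the respiratory chain and ATP synthase had summits at 14 of 32 (43.8%, adjusted p = 3.9e-07 by Fisher's exact test), among them atp-3, nuo-2 and cox-5B. Translation initiation factors (9 of 25), proteasome subunits (11 of 33), RNA polymerase subunits (7 of 22) and mitochondrial ribosomal proteins (12 of 66) were also higher, with Fisher's exact adjusted p of 0.00018, 8.6e-05, 0.0022 and 0.0081. Aminoacyl-tRNA synthetases (5 of 31), kinesins (3 of 13), vacuolar ATPase (2 of 20) and potassium channels (2 of 54) did not pass. Against genes in the relaxed list, respiratory genes (adjusted p = 0.0250) and Sm proteins (0.0346) alone passed Fisher's exact test.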
